A study of Bacillus thuringiensis with 6 samples.

How the data were processed

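The series holds 6 one-colour Agilent arrays of Bacillus thuringiensis serovar kurstaki strain HD73, a spore-forming soil bacterium that makes insecticidal crystal proteins. Per the labels, cultures grew in LB medium at 30 °C with shaking at 220 rpm to an OD600 of 0.7, and the treated cultures received 28 mM NaOH for 10 min before RNA extraction. There were 3 control arrays and 3 alkaline arrays, grouped by their titles. The labels do not say whether control cultures were kept for a further 10 min without NaOH, nor whether the 3 replicates of a group were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

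Per the labels, total RNA was treated with DNase, amplified and labelled with Cy3. Per the submitters' processing notes, the images were read with Agilent Feature Extraction 10.7. Per the file headers, the processed signal of each spot is an intensity on a linear scale, already background-subtracted and detrended within its array, with no scaling between arrays. The deposited flags for spots well above background, saturated spots and outlier spots hold 0 or 1 per spot and are of another kind than a measurement. The authors also deposited a table of log2 values for 14890 probes, all of which matched probe names of the scanner files. Its column medians were 7.27 on each of the 6 arrays, and the rank correlation of each column with its own array's processed signal rounded to 1.00. The equal medians are those of values scaled between arrays, by a method not given in the sources used here. The values are on a log2 scale and rise with the intensity, while any centring stays unknown.

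The array carried 9722 features, measured with 14890 probes, and the features with positional names lay on 47 contigs. Of the features, 5737 were open reading frames (ORFs), 3667 were regions named as untranslated and 318 had no positional name. The regions named as untranslated had a median length of 200 bp, and 92.3% began directly after an ORF or at the start of a contig, so they are called gap regions here. The strand their probes read is not stated in the names. Coordinates are positions on the contigs of the array design, and the genome build is not given in the sources used here. The names of 355 ORFs were cut short and carried no complete coordinates. The files do not pair the feature IDs with gene names, so the 30 gene lists fixed before the data were examined could not be matched and were not run. The limma test, its filter and thresholds, the naming rule and most alternatives were fixed at the same time. Those chosen after seeing the data were spike-in scaling, the filter that asks only the brighter group to be well above background on all its arrays, the brightest probe for the named ORFs, and all alternatives for the median level, contigs, runs and gap regions. For the same reason the rule for named genes was applied without its requirement of a symbol or product text, and its parts on list members and on specific genes could not be used.

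That rule took ORFs with adjusted p under 0.05, a log2 change of at least 1, a probe well above background on at least 2 arrays of each group and no overlap between the values of the groups, which chance gives in 10% of features with 3 arrays against 3. The 2 largest rises and the 2 largest falls among the 1320 ORFs that met it are named by ID, in place of the longer lists of named genes that the rule would give. The groupings by kind of feature, contig, level and run of neighbouring ORFs were chosen after the names in the files had been seen.

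From the deposited intensity values, log2 of the processed signal was taken and the 75th percentile of each array's non-control spots was subtracted. Control spots and 109 outlier spots were left out, and 0 spots were saturated. Spots of a probe and then probes of a feature were averaged on the log2 scale. Among 1297 ORFs with 3 probes above background on all arrays, the median SD between probes of the log2 change was 0.10, and in 406 of 407 that changed at least 2-fold the probes had the same sign. Of the 5737 ORFs, 3017 had 1 probe and could not be checked in this way. A feature was tested if a probe was well above background on all arrays of at least 1 group, which left 7730 features. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9.

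The array also carries 10 probes for E1A spike-in RNA, artificial RNA supplied for one-colour labelling. The step at which it was added, and the amount, are not given in the sources used here. The 8 spike-in probes with at least 90% of spots well above background on every array gave each array's mean spike-in level, which served as a second scaling. This scaling was chosen after seeing the data.

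Contigs with at least 20 tested ORFs were tested with camera at a preset inter-gene correlation of 0.01. A run was a series of at least 3 tested ORFs on 1 strand with at most 100 bp between neighbours, and calls were shuffled over the ORFs of all runs 10000 times. Gap regions and ORFs were compared within bins of 1 log2 unit of their mean level over all 6 arrays, with 1000 shuffles of the 2 kinds within bins. On simulated data with the real means and spread and 200 of 7722 features changed, limma recovered 1.52% of changes of 1 log2 unit, 37.3% of 2 units and 64.2% of 3 units, with 3 false calls. With a larger share changed, as in the real comparison, it recovered 41.0%, 79.1% and 91.4%, and 3.46% of calls were false. The simulated values were normal and independent between features, with the same spread in both groups and no slide effect. The real arrays need not meet these conditions, so these rates need not hold for them. The number of arrays limits the precision.

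Arrays lay on 2 slides. Slide 1 held replicates 1 and 2 of both groups and slide 2 held replicate 3 of both groups, and each slide had its own scan. The replicate numbers come from the titles. Deviations from the group means correlated between arrays of the same number at 0.29, 0.15 and 0.28 over features, each over 0.1. The slide 1 arrays of different number also passed 0.1, at 0.11 and 0.26, so these values do not establish a pairing by number. The main test used the group only, with the replicate number as a block in an alternative. Control replicate 2 correlated more with alkaline replicate 1, at 0.26, so numbers 1 and 2, which share a slide, were not told apart. The deposited files and the titles give alkaline replicate 3 different numbers, which leaves its pairing uncertain. The alternatives were quantile, median and spike-in scaling, normexp background correction with an offset of 50, other filters, the replicate block, the slide block, slide 1 alone, eBayes with trend and robust, the authors' deposited table, the brightest probe and each array left out. The scanner files used here give no mean signal, so normexp ran on the median signal and median background.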

Results

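Transcript levels of B. thuringiensis HD73 were measured on 6 arrays, 3 from control cultures and 3 from cultures exposed to 28 mM NaOH for 10 min. The comparison addresses how the bacterium responds within minutes to an alkaline medium. On the control arrays 85.7%, 86.5% and 85.0% of the 15160 non-control spots were well above background, against 67.0%, 62.9% and 79.7% on the alkaline arrays. Correlations over features lay between 0.945 and 0.993 among control arrays, between 0.908 and 0.980 among alkaline arrays, and between 0.817 and 0.931 across groups. The highest values within groups, 0.993 and 0.980, were between replicates 1 and 2, which share slide 1. Alkaline replicate 3 correlated at 0.931 with control replicate 3 on its own slide, against 0.927 and 0.908 with alkaline replicates 1 and 2. The arrays thus differed by slide as well as by group.

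Most of the transcriptome was dimmer after alkaline exposure when set against the spike-in RNA. The median feature lay at -5.30 ± 0.35 log2 units from the spike-in mean in controls and at -7.76 ± 0.40 in alkaline samples (SD, n = 3), which is 5.49-fold lower. The spike-in probes themselves were at 12.07 ± 0.19 and 12.16 ± 0.29 (SD, n = 3). With spike-in scaling 6148 of 7730 features fell and 43 rose (limma, Benjamini-Hochberg adjusted p under 0.05). The number that rose was 26 without control replicate 2, 80 without alkaline replicate 3 and 70 with the slide as a block. Among the 5299 tested ORFs the middle of the distribution ran from 3.04-fold to 10.3-fold lower, with a median of 5.61-fold. The 3 control values of the median feature lay above the 3 alkaline values, and a two-sided exact permutation test gave p = 0.1, the smallest p that 3 against 3 allows. The spike-in level itself gave p = 0.8 in the same exact test. The fall was 7.38-fold on slide 1 and 3.03-fold on slide 2. The 10 brightest features made up 12.9% ± 0.819 of the signal in controls and 24.1% ± 5.94 in alkaline samples (SD, n = 3).

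**Figure D1:**
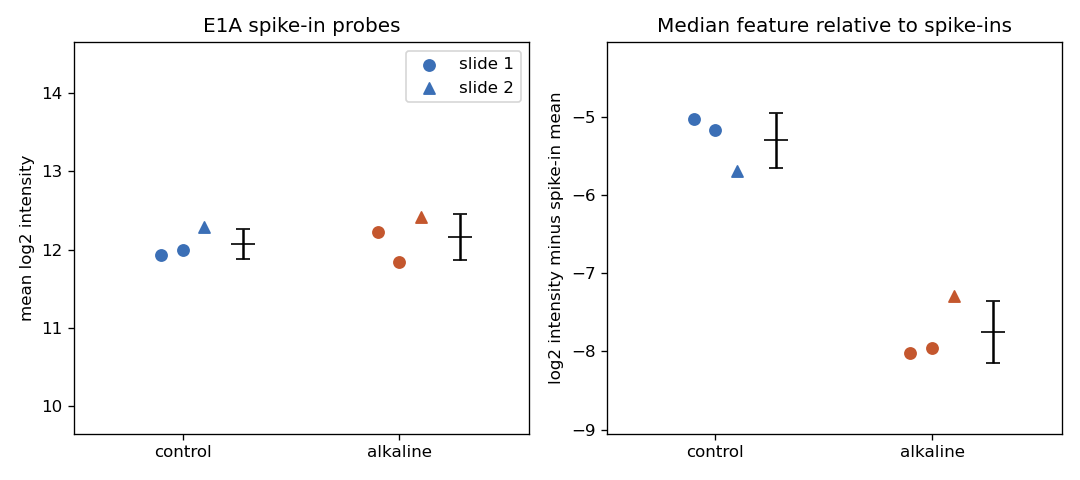
The left panel plots each array's mean log2 intensity of the E1A spike-in probes and the right panel the median feature's log2 intensity minus that mean, with circles for slide 1, triangles for slide 2, and a black bar for the group mean and SD (n = 3). Spike-in means were 12.07 in controls and 12.16 in alkaline samples, while the median feature lay at -5.30 and -7.76.

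Relative to the rest of the transcriptome, 1618 features rose and 1080 fell after alkaline exposure. The largest rises were in a pair of adjacent ORFs on the minus strand of contig3509, contig3509-orf00425_377369-376938 and contig3509-orf00423_376902-376210, which rose 191-fold and 188-fold. Among ORFs well above background on at least 2 arrays of each group, the largest falls were in contig3240-orf00019_6727-7773, which fell 42.7-fold, and contig3236-orf00005_2071-893, which fell 41.3-fold. Each of the ORFs named by ID was measured with 1 probe. The changes are relative to the 75th percentile of each array, under which the median tested feature moved by 0.18 log2 units, against -2.38 with spike-in scaling.

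The ORF contig3509-orf00425_377369-376938 went from -2.98 ± 0.55 to 4.60 ± 0.90 log2 units relative to the 75th percentile (SD, n = 3), a change of 7.58 with an SE of 0.52 and a limma adjusted p of 0.00241. Its neighbour contig3509-orf00423_376902-376210 went from -4.00 ± 0.33 to 3.56 ± 0.87 (SD, n = 3), a change of 7.56 with an SE of 0.48 and a limma adjusted p of 0.00193. With spike-in scaling the pair rose by 5.02 and 5.01 log2 units. The gap region between positions 377370 and 377501, next to the pair, rose 17.6-fold (limma adjusted p = 0.0105), but with spike-in scaling its change of 1.58 log2 units did not pass (limma adjusted p = 0.0805). The ORF beyond that region, from 377502 to 378242 on the same strand, had a log2 change of 0.03 (limma adjusted p = 0.94). On the other side of the pair, the gap region from 375755 to 376209 had a log2 change of 0.90 that did not pass (limma adjusted p = 0.34), nor did the 0.72 of the ORF from 374843 to 375754 (limma adjusted p = 0.112). The files do not pair these IDs with gene names.

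The ORF contig3240-orf00019_6727-7773 went from 5.94 ± 0.08 to 0.52 ± 0.44 log2 units (SD, n = 3), a change of -5.42 with an SE of 0.32 and a limma adjusted p of 0.00193. The ORF contig3236-orf00005_2071-893 went from 5.11 ± 0.06 to -0.26 ± 0.26 (SD, n = 3), a change of -5.37 with an SE of 0.28 and a limma adjusted p of 0.00168. With spike-in scaling these ORFs changed by -7.97 and -7.92 log2 units.

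In all, 2698 of 7730 features changed, 2622 of them at least 2-fold, of which 1575 rose and 1047 fell (limma, Benjamini-Hochberg adjusted p under 0.05). The split depended on the scaling. Quantile scaling gave 1276 higher and 1282 lower features, the values in the authors' deposited table gave 1217 higher and 1199 lower, normexp correction 3787 and 530, and spike-in scaling 43 and 6148. Under normexp 162 of the 2698 features were called in the opposite direction. Spike-in scaling moves the change of every feature with values on all arrays by the same -2.55 log2 units, so a fall of such a feature cannot turn into a rise. After that shift, of the 1618 features higher at the 75th percentile, 466 were lower against the spike-ins, 1109 were not called and 43 were higher. Single arrays moved the count. Without control replicates 1, 2 and 3 in turn, 524, 320 and 2383 features changed. Without alkaline replicates 1, 2 and 3 in turn, the counts were 1463, 1596 and 4241. With the slide as a block 3467 features changed, 2057 higher and 1410 lower. Slide 1 alone gave 5012. The log2 changes on the 2 slides correlated at 0.62 over 7726 features, and 70.8% of these had the same sign on both.

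Of the falls, 89 were in features not well above background on any alkaline array. The dim group was set to the lowest signal among probes well above background, or to its own signal if higher, which left a bound over 1 for 61 of the 89 and of at least 2-fold for 24, the largest being at least 8.44-fold lower. Of the rises, 5 were in features not well above background on any control array, with a largest bound of at least 21.8-fold higher.

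The 43 features that rose against the spike-ins, a number that ranged from 26 without control replicate 2 to 80 without alkaline replicate 3, comprised 29 ORFs, 13 gap regions and 1 unnamed feature, with a median rise of 4.40-fold. All 43 were also called higher relative to the 75th percentile.

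**Figure D2:**
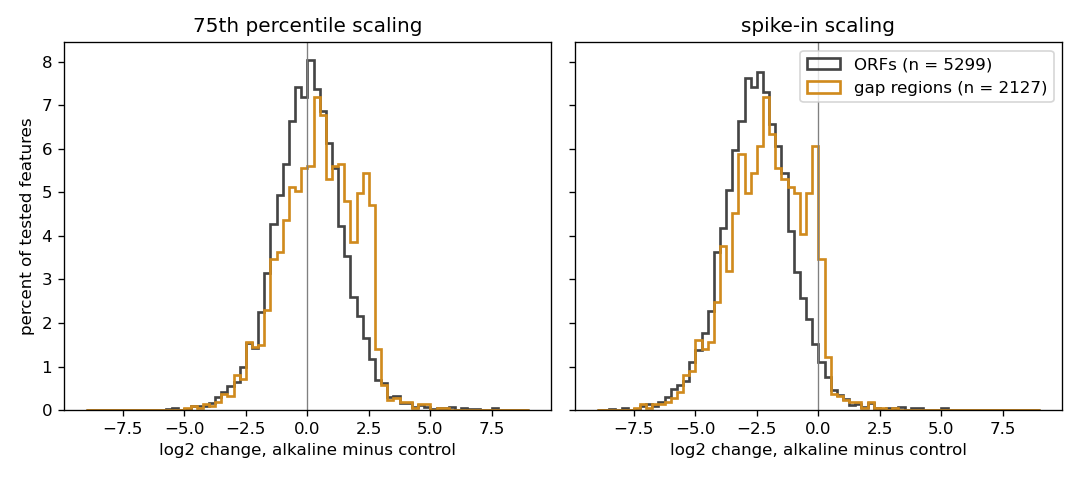
Outlines give the percent of tested ORFs and gap regions in each interval of log2 change, alkaline minus control, relative to the 75th percentile (left) and to the spike-ins (right). The median ORF moves from 0.06 to -2.49 between panels, and 15.8% of gap regions against 5.46% of ORFs lie within 0.5 of 0 in the right panel.

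Neighbouring ORFs changed together. In 21 runs of adjacent ORFs on 1 strand every tested ORF rose, and in 8 every tested ORF fell, out of 397 runs with 1607 ORFs. Shuffled calls gave a median of 1 run and at most 6 in either direction (permutation p = 1e-04, the smallest 10000 shuffles can give). Quantile scaling gave 8 rising and 8 falling runs, the values in the authors' deposited table gave 7 and 8, and normexp correction gave 84 and 4. Only 16 runs held both rises and falls, where shuffling gave a median of 86. Log2 changes of adjacent ORFs on 1 strand at most 100 bp apart correlated at 0.68 over 1759 pairs, and those farther apart on 1 strand at 0.27 over 1620 pairs. Divergent neighbours correlated at 0.06 (601 pairs) and convergent ones at -0.003 (635 pairs). These correlations are across genes, which are not independent replicates.

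Of the runs in which every ORF rose, 20 also had every ORF well above background on at least 2 arrays of each group. Among these, the run with the largest median rise lay on the plus strand of contig3515 from 220595 to 225067. Its 4 ORFs rose by a mean of 3.54 log2 units, 11.6-fold, from -5.54 ± 0.64 to -1.99 ± 0.64 (SD, n = 3). The second largest median rise was in a run on the minus strand of contig3517 from 411421 to 420940, which, with 1 further run of 8 ORFs on that strand from 681061 to 689073, was the longest. Its 8 ORFs rose by a mean of 3.50 log2 units, 11.3-fold, from -3.46 ± 0.13 to 0.04 ± 1.17 (SD, n = 3), with a median of 4.20 on slide 1 and 2.10 on slide 2. A run of 3 ORFs on the minus strand of contig3541, from 740597 to 744414, rose 6.02-fold, from 0.85 ± 0.87 to 3.44 ± 0.77 (SD, n = 3). With spike-in scaling the medians of these runs were 0.96, 0.92 and 0.20 log2 units, and 3 ORFs of the contig3517 run were still called higher.

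**Figure D3:**
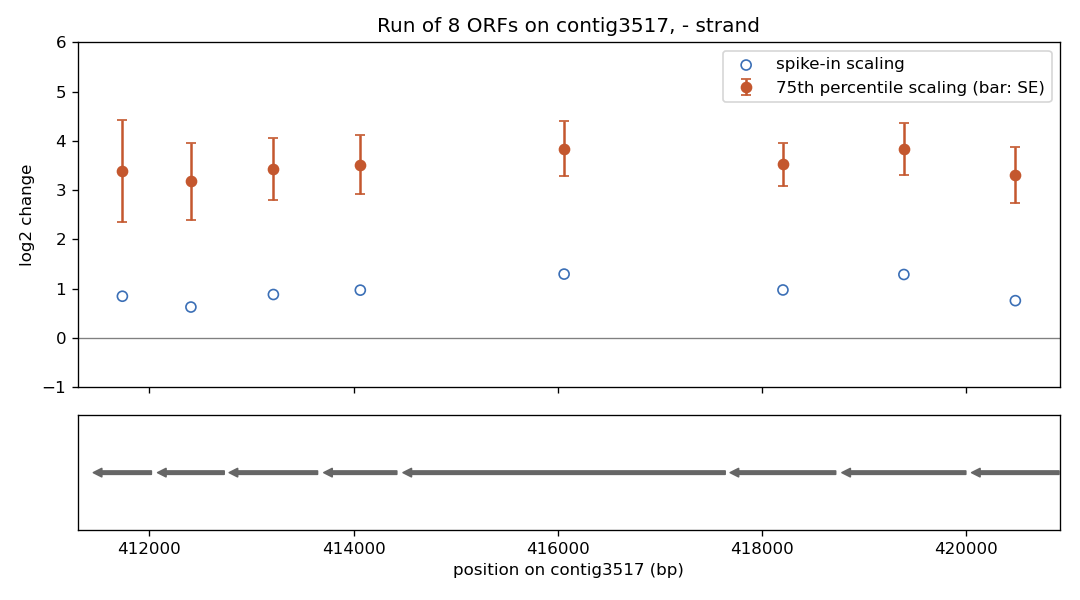
The upper panel plots the log2 change of each of the 8 ORFs against position in bp on contig3517, filled for 75th percentile scaling with the SE as a bar and open for spike-in scaling, and the lower panel maps the ORFs as arrows in their direction. The changes lie between 3.17 and 3.84 with 75th percentile scaling.

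Among the 6 runs above background in the same way in which every ORF fell, the largest median fall lay on the plus strand of contig3355 from 167724 to 170311. Its 3 ORFs fell 6.34-fold, from -0.54 ± 0.52 to -3.20 ± 1.22 (SD, n = 3), with a median of -3.71 on slide 1 and -0.89 on slide 2. On the plus strand of contig3519, 3 ORFs from 273762 to 276111 fell 4.45-fold, from 0.64 ± 0.20 to -1.52 ± 0.46 (SD, n = 3). A further 3 ORFs from 367989 to 370069 on the same strand fell 4.34-fold, from 1.59 ± 0.07 to -0.53 ± 0.96 (SD, n = 3). The medians of these contig3519 runs were -2.75 and -2.89 on slide 1, and -1.09 and -1.49 on slide 2. The longest of the 6 held 4 tested ORFs on the minus strand of contig3543, from 118712 to 122234, and fell 3.30-fold, with a median of -2.39 on slide 1 and -0.61 on slide 2. By the way these runs were chosen, every tested ORF in them had a limma adjusted p under 0.05. With each array left out, the number of runs with every ORF higher ranged from 1 to 32 and with every ORF lower from 0 to 25. With spike-in scaling every ORF was lower in 272 runs and every ORF was higher in 0.

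No contig passed a test for a shift of its ORFs as a group. Of 16 contigs with at least 20 tested ORFs, 0 passed camera (lowest Benjamini-Hochberg adjusted p = 0.335, and 0 at an unadjusted p under 0.05), and 0 passed with an estimated correlation. With the replicate number as a block, 2 contigs were lower, contig3234 and contig77350, each with a camera adjusted p of 0.043, while with the slide as a block 0 contigs passed and both had a camera adjusted p of 0.124. Their ORFs had median log2 changes of -1.74 and -0.42. For contig3234 the change was -1.02 on slide 1 and -2.72 on slide 2, control replicate 3 stood apart with a median level of 4.47 against 1.75 and 2.40, and the estimated correlation between its ORFs was 0.809, against the preset 0.01. For contig77350 the change was -0.46 on slide 1 and -0.57 on slide 2. Its control replicate 3 had a median level of -0.76 against 0.19 and 0.59, and the estimated correlation was 0.268. Without alkaline replicate 3, 1 contig was lower.

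Gap regions fell less than ORFs, with a median of -2.04 log2 units against the spike-ins where ORFs had -2.49. Of 2127 tested gap regions 660 rose and 236 fell relative to the 75th percentile, with a median change of 0.51 log2 units. Of 5299 ORFs 902 rose and 805 fell, with a median of 0.06. At equal mean level gap regions lay 0.58 log2 units above ORFs, where shuffles ranged from -0.16 to 0.16 (permutation p = 0.001, the smallest 1000 shuffles can give). The shuffles treat features as independent, which neighbours are not, so this p does not measure the spread between samples. The difference was 0.76 on slide 1 and 0.35 on slide 2, and it turned to -0.22 in the dimmest bin. It was 0.48 without features at least 0.9 log2 units brighter on the slide 2 control, and 0.34 without features within 0.5 log2 units of no change against the spike-ins, which are chosen by the change itself. Of 1704 gap regions with both flanking ORFs tested, 379 changed more upward and 152 more downward than the mean of their flanks (limma on the difference, adjusted p under 0.05). This comparison was not matched on level, and tested gap regions were dimmer, with a median control level of -3.11 against -1.42 for ORFs. Among the same 1704, 724 gap regions were called, and 380 of these shared the call of a flank. Of 659 gap regions called higher with values on all arrays, 327 lay within 0.5 log2 units of no change against the spike-ins.

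**Figure D4:**
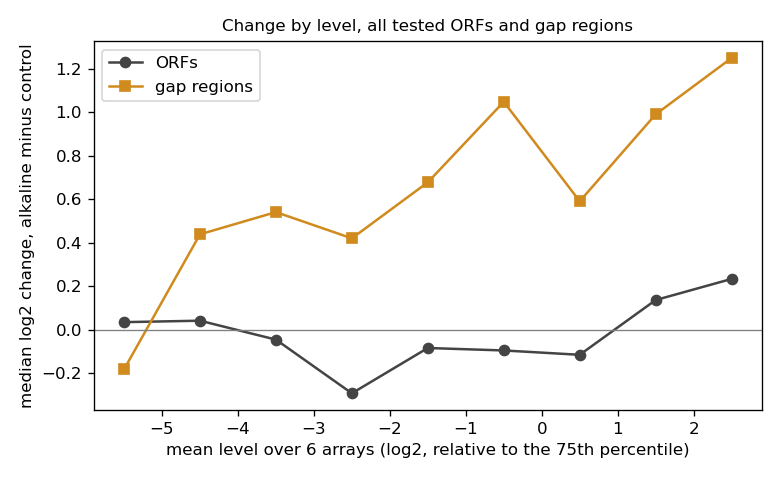
Points give the median log2 change, alkaline minus control, of ORFs and gap regions in bins of 1 log2 unit of mean level over all 6 arrays. Gap regions lie above ORFs in each bin except the dimmest, where the difference is -0.22.

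A group of gap regions differed between the slides in the controls. The 189 gap regions at least 0.9 log2 units brighter on the slide 2 control than on the slide 1 controls, relative to the spike-ins, had a median change between groups of -0.19 on slide 1. The other 1935 gap regions had a median of -2.53. The slide 1 control arrays enter both the choice of the regions and this change. With 1 slide 1 control for the choice and the other for the change, the chosen gap regions had medians of -0.29 and -0.19 in the 2 orders, and ORFs chosen in the same way had -1.11 and -1.28. These controls share a slide and correlated at 0.993, so exchanging them does not separate the choice from a slide effect. On the alkaline arrays the 189 regions were brighter on slide 2 by a median of 1.26 log2 units, against 1.22 on the control arrays, and the 200 ORFs chosen in the same way by 1.75 and 1.63. The control values follow in part from the choice. In the same comparison the other gap regions stood at 0.62 on the alkaline and -0.42 on the control arrays, and other ORFs at 0.73 and -0.66. Of the 189 regions, 132 were called higher relative to the 75th percentile. These 200 ORFs had a median change of -1.02 on slide 1, against -3.02 for other ORFs.

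**Figure D5:**
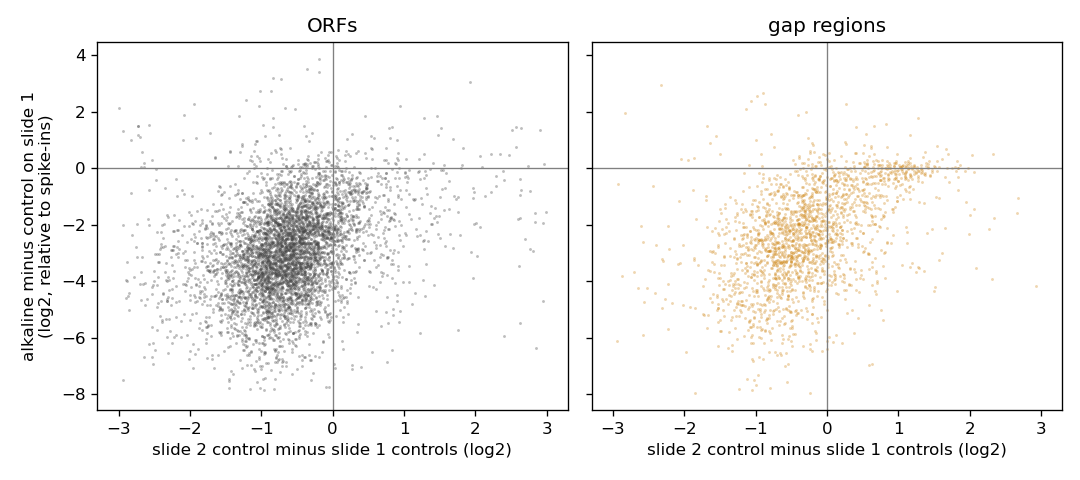
Each point is a tested ORF (left) or gap region (right), with the slide 2 control minus the slide 1 controls on the horizontal axis and the change between groups on slide 1 on the vertical axis, both in log2 units relative to the spike-ins, with features beyond the plotted range not drawn. A group of gap regions lies near 0 on the vertical axis at the right, where the 189 regions beyond 0.9 have a median of -0.19.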

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

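Scaling to the spike-ins, the test of the median level, the filter that asks only the brighter group to be well above background on all its arrays, the brightest probe for the named ORFs, and the alternatives for contigs, runs and gap regions were chosen after seeing the data. In all, 4317 features changed under normexp correction with the 75th percentile, 4302 of them at least 2-fold, and the median tested feature moved by 1.06 log2 units. Normexp with quantile scaling left 1257 at least 2-fold. Slide 1 alone gave 5012 and 4124. Spike-in scaling gave 6191 and 6159, and with the slide as a block 6505 and 6385. The normexp offset of 50 was above the median intensities of the alkaline arrays, 20.9, 16.3 and 37.8. It was below those of the controls, 148, 137 and 112. With quantile scaling normexp gave 1118 higher and 1086 lower features, with a median change of -0.01. The excess of rises under normexp thus came with the 75th percentile scaling and not with quantile scaling. No other offset was tried, and the cause of the other differences in count was not tested. With each array left out the counts ranged from 320 to 4241 and, at least 2-fold, from 320 to 3669, and 318 of the 2698 features were called in the same direction in all 6 of these fits. Of 21 alternatives, 12 left the count of changed features within 1.5 times its value, and 12 of 21 the count at 2-fold. The named ORFs were called in the same direction under all 20 alternatives, with limma adjusted p-values up to 0.0196. Each was measured with 1 probe, so the brightest-probe alternative left their log2 changes as they were by construction. The filters, the blocks and the eBayes setting also leave these log2 changes as they are and move only the p-values. The replicate block gave 2615 features, of which 2348 were shared with the 2698 in the same direction, and called 2 contigs, but ended the call of no named ORF. The median level against the spike-ins was -2.88 on slide 1 and -1.60 on slide 2, and with each array left out it ranged from -2.68 to -2.32. The number of contigs shifted ranged from 0 to 1 with each array left out. The gene list alternatives were not run, since no gene names could be matched. Signal over background limits the alkaline arrays most, where 58.7% of features were well above background on all 3, against 78.8% in controls.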

Other observations

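All tests of explanations in this part were chosen after the results had been seen. The 4 ORFs named by ID and the runs changed against a transcriptome that was dimmer as a whole, and the real grouping gave 2698 changed features with 75th percentile scaling and 6191 with spike-in scaling. The highest count among the other splits of the 6 arrays was 0 in both cases. Thus 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 same-numbered pairs also gave 0. Every split but the real one mixes control and alkaline arrays in each group, so a treatment difference adds to the spread within groups. Such mixing alone can give counts of 0, so the splits cannot decide whether the real counts arose by chance.

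Most features were lower against the spike-ins after alkaline exposure, and an effect of NaOH on the cells' RNA stays open as an untested explanation. A dimmer hybridisation or scan would have lowered the spike-ins too, and they differed by 0.0914 log2 units. The negative control probes, whose log2 signal was low at 1.18 in controls and 0.68 in alkaline samples, did differ, by -0.497. Each slide and scan held both groups, so a shift of a whole slide or scan day would give no difference between groups within it. This follows from the design and not from the values. The smaller of the within-slide falls gave -1.60. A loss of messenger RNA in handling or labelling stays open and cannot be told apart from the treatment. An even loss alone would have moved all ORFs alike, and their interquartile range was 1.75 log2 units, but a loss joined with changes of single transcripts could give that range.

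The smaller fall of gap regions may be technical in part. Dim signal and residual background would have left gap regions and ORFs of equal level alike, and they differed by 0.58 log2 units, or 0.48 without features brighter on the slide 2 control. Without those near the spike-ins, which are chosen by the change itself, the difference was 0.34. In the dimmest bin it turned to -0.22, so dim signal stays open there. A small number of stable RNAs would have left most gap regions at the level of ORFs, and 63.8% lay above the ORF median of their level. The cut-off for that share was set after the results had been seen. Of the gap regions, 15.8% lay within 0.5 log2 units of no change against the spike-ins. A subset of that size could also raise the share, so it does not decide the question. A signal in part of the gap regions that follows the slide and not the treatment stays open. With 1 slide 1 control for the choice and the other for the change, regions brighter on the slide 2 control had a median change of -0.29 in the order that gave the larger change. ORFs chosen alike also shifted by up to 1.83 log2 units against other ORFs, to medians of -1.11 and -1.28, so the choice itself could give at least part of the shift. A biological difference in these RNAs stays open as well, as untested.

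The log2 changes spread less over features on slide 2, with an SD of 1.21 against 1.74 on slide 1. An interaction of slide and treatment passed for 1148 features (limma, adjusted p under 0.05), with the spread taken from slide 1 alone, since slide 2 held 1 array of each group, and with 2 residual degrees of freedom. A compressed signal scale on slide 2 is argued against by the spike-in probes, whose slope between slides was 0.997. Slide, scan day and a weaker response of that culture cannot be told apart in this design.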
